A study of Triticum aestivum with 72 samples.

How the data were processed

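Transcript levels were measured in developing seeds of bread wheat with a 1-colour Affymetrix wheat array. The series holds 72 arrays from 36 lines of the mapping population RL4452 × AC Domain, with 2 arrays per line, each from a separate biological replicate of field-grown plants. Seeds were taken 5 days after anthesis, and polyadenylated RNA was labelled with biotin, per the labels. The arrays are numbered replicate 1 and replicate 3 in 35 lines, and replicate 2 and replicate 3 in line H9.

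The deposited values are summarised probe set intensities on a linear scale, from 6.025 to 29610, with no value at or below 0. RMA is the tool named in the submitters' processing notes, with no version, and whether all arrays were summarised together is not given in the sources used here. RMA values are usually deposited as log2, and these were not, so log2 was taken here with a pseudocount of 0. The median intensity per array lay between 39.8 and 43.5. For arrays such as these, the number of arrays limits the precision of every value, and no depth in counts exists. A text record of the array run accompanies each array. It gave the hybridisation day, of which there were 12, and nothing else was taken from it.

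The table holds 61290 probe sets. The 111 Affymetrix control probe sets were left out of the tests, and the other 61179 were all tested with no filter on low values. The supplied annotation gives 1 gene symbol to 1273 probe sets, several to 0 and none to 60017. The named probe sets stand for 771 genes, of which 770 were found in the supplied RefSeq table, and 102 carry a name other than a locus number. No genomic coordinates are printed, because the build behind the annotation of the array is not named. Most genes therefore appear by their locus symbol, and probe sets without a symbol are unnamed here, not without a gene. Wheat carries near-identical gene copies on its 3 subgenomes. How far 1 probe set reads several copies, and how far a sequence difference under a probe changes its signal, was not analysed here, since values of single probes were not in the table.

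Differences between lines were tested with limma 3.58.1 in R 4.3.3, with 1 mean per line, a moderated F-test and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The intraclass correlation, the share of variance between arrays that lies between lines, was computed per probe set with negative estimates kept. A probe set was said to fall into separate classes of lines when the sorted line means had a gap of at least 0.5 log2 units with at least 6 lines on each side and no array on the other side from its line. This count was set beside 20 simulations with normal line effects. Replicate 3 was compared with replicate 1 in limma with the line as a block, in the 35 lines with both. Lines F38a and F38b were compared in the fit of all lines, beside all 630 pairs of lines. For each array the nearest array was found by Pearson's correlation over the 10 percent most variable probe sets, and the count of arrays nearest to their own line was set against 100000 random pairings.

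Of 19 gene lists fixed before the data were examined, 8 had no member, because the supplied tables give symbols and synonyms but no descriptions, and 2 had the 5 members a test required. A further 11 lists were drawn up from the gene synonyms before any expression value was examined, of which 9 could be tested. They overlap in part with the fixed lists. The mean of each list over its members was tested over lines against 100000 random assignments of arrays to lines, one-sided for a large F, and its shift between replicates was tested with camera at a preset correlation of 0.01. Benjamini-Hochberg adjustment ran over the 11 lists tested.

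The genes named in the text follow a rule set before the data were examined. Named were the 15 genes with the largest F and the 6 with the largest range of line means among those past the threshold, and in each fixed list the 3 members with the smallest adjusted p and the 1 with the largest. The 8 largest rises and the 8 largest falls between replicates past the threshold were named as well. The rule also covered the 8 widest gaps and the 5 largest differences between F38a and F38b, and no gene met those parts. Genes outside the rule are marked as such where they appear.

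Each test was tested on simulated data drawn from the real means and spreads of the 61179 probe sets, with 50 changed probe sets per size. The line test recovered 8%, 30%, 96% and 100% of probe sets with an intraclass correlation of 0.3, 0.5, 0.7 and 0.9. When 12 lines were given the wrong partner array, these fell to 2%, 10%, 16% and 58%. With no line effect at all, 0 were called. The noise in all these draws was independent between probe sets and between arrays, which real arrays need not be. When the real arrays were assigned to lines at random, 63 of 99 assignments gave 0 calls and the highest count was 297. The replicate comparison recovered 64%, 92%, 100% and 98% of changes of 0.25, 0.5, 1 and 2 log2 units. The search for separate classes recovered 32%, 94%, 94% and 96% of class differences of 1, 2, 3 and 4 log2 units, and 0 of 200 when 12 lines had the wrong partner.

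The alternatives were median centring of each array, quantile normalisation, filters on low values, an offset of 16 before the log, other thresholds and moderation, the replicate number, the hybridisation day, the first principal component and the 3 prime to 5 prime signal ratio of 7 control genes as blocks or covariates, and each array or line left out in turn. A comparison of the arrays over probe sets that split all 72 arrays into a high and a low level was added after the data had been seen. So were fits without lines or arrays picked by such comparisons, and tests within single hybridisation days. Several gap widths and several limits on arrays out of place were looked at before the settings given here were kept. Labels were used as deposited throughout, and no array was moved to another line. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the annotation, the array comparison and the plots.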

Results

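Seeds of 36 lines from the wheat cross RL4452 × AC Domain were profiled 5 days after anthesis. Each line was represented by 2 arrays, 72 in all, and neither parent was among them. The series title names expression level polymorphism as its subject, so the first question was which transcripts differed between lines by more than the replicates of a line did. After log2 transformation the array medians lay between 5.32 and 5.44.

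A starch synthase gene and a beta-glucosidase gene were among the named genes that differed most between lines. LOC543395, also named GBSS-I and Wx-A1, encodes the granule-bound starch synthase that makes amylose in the grain. Its line means ran from 7.08 in A35 to 10.95 in A81 on the log2 scale, a range of 3.87 with a residual SD of 0.54 (limma moderated F-test, F = 10.4, adjusted p = 2.64e-07). LOC780595, also named TaGlu1a, a beta-glucosidase, ran from 6.69 in H8 to 10.52 in B65, with a residual SD of 0.73 (limma, adjusted p = 0.00015). The largest F among named genes belonged to LOC100037572, whose line means ran from 6.59 in G13 to 9.76 in C10 (F = 11.2, limma adjusted p = 1.29e-07). The intraclass correlation was 0.812 for LOC543395, 0.669 for LOC780595 and 0.826 for LOC100037572. For LOC543395 the values of single arrays ran from 6.90 to 11.19, and those of LOC780595 from 5.56 to 11.01. Some of these end lines also differed in the log2 3 prime to 5 prime ratio of the control genes. It was 1.478 and 1.609 in the arrays of A81, 1.511 and 1.532 in H8, and 0.755 and 0.564 in G13. RNA quality was thus partly shared within lines. These 3 genes stayed past the threshold with the ratio as a covariate.

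**Figure D1:**
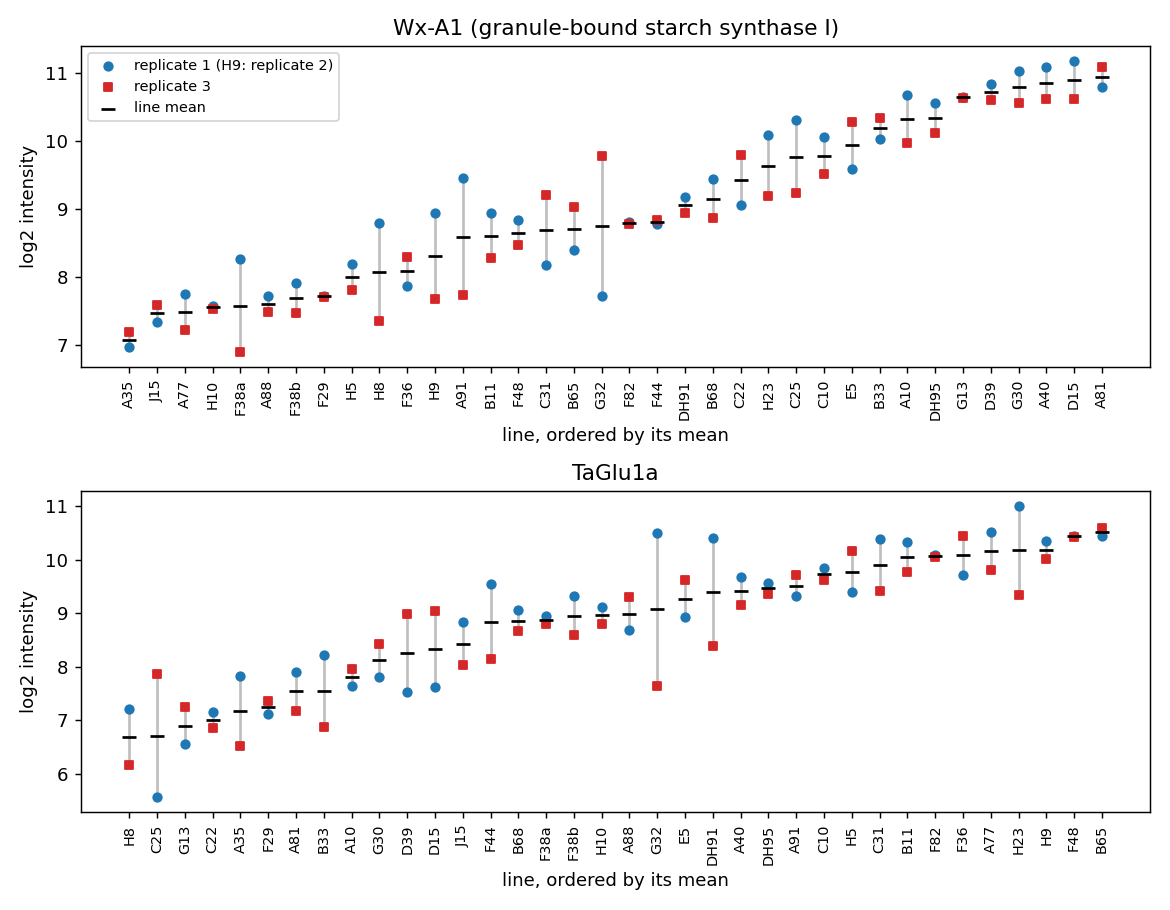
Log2 intensity of Wx-A1 (LOC543395, top) and TaGlu1a (LOC780595, bottom) in each of the 36 lines, ordered along the x axis by line mean. Blue circles are replicate 1 arrays (replicate 2 for H9), red squares are replicate 3 arrays, black dashes are line means and grey bars join the arrays of a line; the Wx-A1 means climb from 7.08 to 10.95 without a clear break.

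Other named genes also had wide ranges of line means. LOC542839 spanned 4.31 log2 units (B11 to C25), LOC543235 spanned 4.04 (B11 to A81) and LOC543492 spanned 4.03 (B11 to F29). LOC780602 spanned 3.89 (A10 to C10), LOC778392 spanned 3.62 (B65 to A81) and LOC542796 spanned 3.56 (G13 to C31). LOC542838 spanned 3.47 (B11 to A81), LOC543150 spanned 3.30 (C10 to F48) and LOC606323 spanned 3.27 (H9 to B33). Narrower ranges were found for LOC778400 at 2.28, LOC543048 at 1.52, LOC543436 at 1.35, LOC780636 at 0.99 and LOC780640 at 0.95. B11 was at the low end for LOC542839, LOC543235, LOC543492 and LOC542838, and C25 at the high end for LOC542839. Both are among the 12 lines with unmatched arrays, so the arrays of each may not be of the same line. For these genes the B11 arrays were nonetheless similar, since the B11 mean lay close to the lowest single array. It was 8.83 against 8.81 for LOC542838, 5.44 against 5.38 for LOC543235, 4.96 against 4.76 for LOC542839 and 5.56 against 5.25 for LOC543492. Without the 12 lines the ranges were 3.63 for LOC542839, 3.69 for LOC543235, 3.90 for LOC543492 and 3.09 for LOC542838. These values are of 1 probe set per gene, whose limma adjusted p in all lines lay between 1.54e-06 for LOC780602 and 0.0091 for LOC542839. In these probe sets, LOC543395, LOC780595, LOC100037572 and the genes listed so far in this paragraph passed the threshold in each of the 72 fits that left out 1 array. Other probe sets of a gene could differ. Those that also passed spanned 1.95 for LOC778392 and 2.67 for LOC542838 (both A77 to G13), 2.59 for LOC543150 and 2.40 for LOC778400 (both G13 to F48). Another probe set of LOC780602 did not pass (limma adjusted p = 0.766). Outside the rule for named genes, and chosen after their values were seen, LOC543318 (BMY1), a beta-amylase, ran from 11.96 in H8 to 13.02 in H9 (limma adjusted p = 0.0338). LOC542973 (Trx-M), a plastid thioredoxin, ran from 9.75 in B33 to 11.11 in F82 (limma adjusted p = 0.0072), and was chosen in the same way. The values of BMY1 and Trx-M with the 3 prime to 5 prime ratio as a covariate were not examined.

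Over the whole array, 1553 of 61179 probe sets differed between lines (2.54%, limma, adjusted p under 0.05), and 8508 did so at an unadjusted p under 0.05. The median range of line means among the 1553 was 1.86 log2 units, the largest was 8.30, and 1413 had a range of at least 1. Among probe sets with a gene symbol, 44 of 1273 passed (3.46%), from 37 genes. The median intraclass correlation over all probe sets was 0.0641, with quartiles of -0.0536 and 0.188, and 1055 probe sets exceeded 0.5. A range of line means of at least 1 was found for 15638 probe sets, most of which did not pass the test. In 12 lines the arrays did not match each other, as described among the other observations. Leaving out the replicate 1 array of B33 gave 2571 probe sets, and leaving out the replicate 3 array of B65 gave 3075. Each of these leaves its line with an array far from the mean array: B33 replicate 3 (median deviation 0.256, first principal component 115.8) or B65 replicate 1 (0.291 and 86.1). Without the 3 farthest arrays, which include both, 1808 passed. With the 3 prime to 5 prime ratio of the control genes as a covariate, 1294 passed. Without those 12 lines, an exclusion chosen after the data were seen, 2438 probe sets passed in the remaining 24. Those lines were picked because their arrays disagreed, which the F-test also measures, so a rise is partly built into the exclusion.

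Among the lists fixed beforehand, storage protein transcripts were close to the bottom of the scale and did not separate the lines. The gamma-gliadin gene LOC543214 had a mean of 3.50, the low-molecular-weight glutenin gene LOC543213 a mean of 4.28, the gliadin gene LOC543212 a mean of 4.51 and the gliadin gene LOC543385 a mean of 3.37. Of the 11 storage protein probe sets, 0 passed over all probe sets in limma and 0 passed adjusted over the list alone, and the list mean gave a permutation adjusted p of 0.671. Peroxidases and glutathione transferases, with LOC543108 (PER1) and LOC543412 (GSTZ1), had 0 of 5 members past the threshold by either count and a list-mean permutation adjusted p of 0.0508.

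Fixed lists with fewer than 5 members were described without a list test. In starch synthesis, LOC543395 passed over all probe sets, and both it and LOC543299 (AGP-S), a small subunit of ADP-glucose pyrophosphorylase, made the count of 2 members adjusted over the list alone. AGP-S line means lay 0.73 log2 units apart at most (limma adjusted p = 0.296). In the photosynthesis list, LOC543290 (PsbP), a subunit of the oxygen-evolving complex, ran from 11.39 in B33 to 12.68 in G13 (limma adjusted p = 0.0438). LOC543291 (PsbO), of the same complex, ran from 11.82 to 12.94 between the same lines (limma adjusted p = 0.283). Of its 3 probe sets, 1 passed over all probe sets and 3 passed adjusted over the list alone. The PsbP call was lost with quantile normalisation (limma adjusted p = 0.116), with the hybridisation day as a block (0.133) and with the 3 prime to 5 prime ratio as a covariate (0.123), and it held in 25 of 72 fits without 1 array. B33, the low end for PsbP, PsbO and Trx-M, holds 1 of the arrays farthest from the mean array. Ribosomal protein genes had 0 of 3 probe sets past the threshold over all and 1 adjusted over the list alone, with LOC543077 (RPL9) at an adjusted p of 0.0869 and LOC606342 (RPS29) at 0.776 in limma.

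The small heat shock protein gene LOC543277 (hsp16.9A), whose product protects proteins under heat, had the widest spread of line means among the members of fixed lists, 8.22 log2 units. Its line means ran from 4.25 in G13 to 12.47 in B68, but the residual SD was 2.41, the intraclass correlation 0.235 and the limma adjusted p 0.337. It counted as 1 member adjusted over the list alone, in a list of 1. The dehydrin and late embryogenesis list (COR410 and LOC543476) had 0 of 2 members past the threshold by both counts. So did the grain inhibitor list with the serpins LOC543382, LOC543376 and LOC542985 (0 of 3), and the defence list with the thionin LOC543413 and LOC543292 (PR5, 0 of 3). XTH in the cell wall list (0 of 1) and PER1 in the embryo and aleurone list (0 of 2) did not pass by either count. The lists for starch and sugar breakdown, cell division, maternal proteases, MADS-box factors, hormone metabolism, anther and pollen, transfer cells and transposons had no member.

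**Figure D2:**
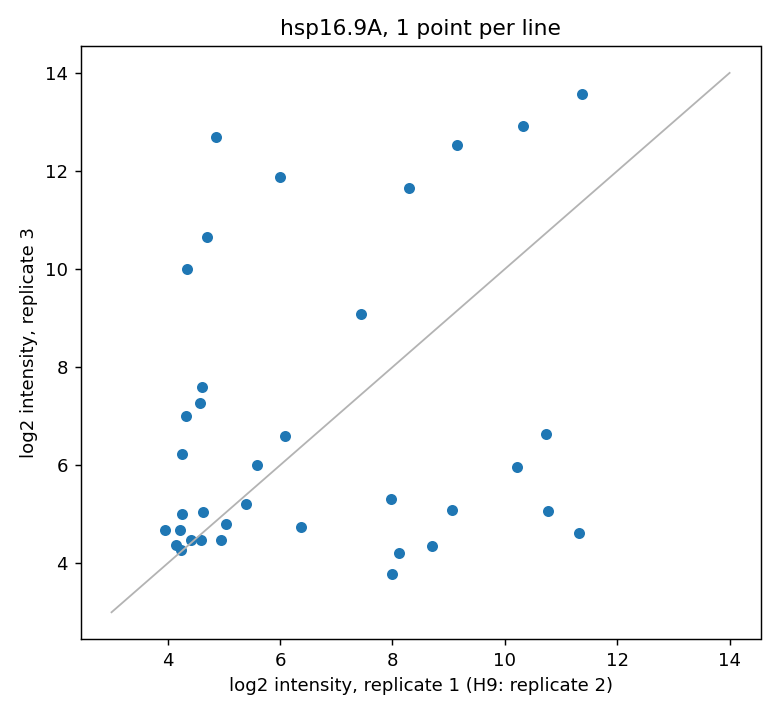
Log2 intensity of hsp16.9A (LOC543277) in the replicate 1 array (x axis; replicate 2 for H9) and the replicate 3 array (y axis) of each line, 1 point per line, with the line of equal values in grey. Values span 3.78 to 13.57, and several lines are high in only 1 of their arrays.

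Of the 11 lists tested, 2 had a line effect in their mean, both drawn up from gene synonyms. Starch and fructan metabolism, with LOC543395, BMY1, LOC543441 (1-FEH) and AGP-S, had a permutation adjusted p of 0.0361 and a list-mean intraclass correlation of 0.406. Of its 10 probe sets, 2 passed over all probe sets and 4 passed adjusted over the list alone. The list mean was not scaled and its line means spanned 0.476, while LOC543395 alone spanned 3.87. How far that 1 probe set carried the call was not tested. Photosynthesis genes, with PsbP, PsbO, petC, FBP, LOC543283 (PRK) and the large Rubisco subunit gene LOC100049018 (rbcl), had a permutation adjusted p of 0.0238 and a list-mean intraclass correlation of 0.46. Of its 36 probe sets, of which 28 belonged to rbcl, 1 passed over all and 3 passed adjusted over the list alone. The starch call was lost with median centring (permutation adjusted p = 0.0646) and the photosynthesis call with quantile normalisation (0.0745). With the list median in place of the mean 0 lists passed, and with values scaled to SD 1 the count was 1. Without 1 array at a time, the starch list was called in 58 of 72 fits and the photosynthesis list in 71. The count of lists was 0 without A81 replicate 3, and 1 without A81 replicate 1, either array of G13, A88 or A35, F29 replicate 3, B68 replicate 1, A40 replicate 1, F38a replicate 3, H23 replicate 1 or A77 replicate 3. It was 4 without G32 replicate 3, DH91 replicate 1, B68 replicate 3, A10 replicate 1, B65 replicate 3 or H9 replicate 3. It was 5 without either array of F36, D15 replicate 3, A10 replicate 3, B65 replicate 1 or H9 replicate 2, and 6 without C31 replicate 1.

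The other 9 tested lists did not pass, 3 of them by a narrow margin, and the calls of lists changed with the settings described under the dependence on processing. The permutation adjusted p was 0.0502 for embryo and ABA-responsive proteins, 0.0502 for defence and antioxidant proteins, 0.252 for translation factors and ribosomal proteins, and 0.337 for serpins, amylase inhibitors and thionins. It was 0.377 for gliadins and glutenins, 0.554 for tubulins and 0.561 for core histones. Raftins of the anther and gibberellin 20-oxidases, with 4 probe sets each, were not tested as lists, and 0 of their members passed over all probe sets in limma.

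A single segregating locus would place the line means of a transcript in separate classes. With the labels as deposited, 0 probe sets met the definition of separate classes with both arrays of every line on the same side, against a mean of 0.2 and a highest count of 1 in 20 simulations without such classes. This 0 says little about single loci, because the search recovered 0 of 200 simulated classes when 12 lines had the wrong partner array. A gap of at least 0.5 was present in 259 probe sets, each with at least 1 array out of place. LOC780602 had a gap of 0.63 with 4 arrays out of place, and LOC543395 a gap of 0.31 with 2. Without the 12 lines whose arrays did not match, an exclusion chosen after the data were seen, 135 probe sets met the definition, and simulations of the 24 lines without classes gave a mean of 30.25 and a highest count of 41. The simulations do not repeat the picking of lines for disagreement over bimodal probe sets, which itself raises the real count, so how far 135 exceeds chance is not known. The named gene among them was LOC780602, with a gap of 1.46 and 12 lines on the high side. Both gaps given for LOC780602 are those of 1 probe set. Another probe set of this gene did not pass the line test in all lines (limma adjusted p = 0.766, intraclass correlation -0.0225). The classes are thus shown for that probe set, not for the gene as a whole.

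LOC543074 (TPC1), a calcium channel of the vacuole, was higher in replicate 3 by 0.39 log2 units (SE 0.094, 26 of 35 lines, limma adjusted p = 0.0236). LOC543418 was higher by 0.67 (SE 0.18, 23 of 35 lines, limma adjusted p = 0.0373), and an rbcl probe set by 0.24 (SE 0.059, 29 of 35 lines, limma adjusted p = 0.0258). That probe set, 1 of the 28 of rbcl, had a mean of 3.74, close to the bottom of the scale. LOC543333 (Hmgb3), a chromatin protein of the high mobility group, fell by 0.36 (SE 0.075, higher in 8 of 35 lines, limma adjusted p = 0.0149). LOC100037651 fell by 0.58 and LOC100049047 by 0.57, higher in 9 and in 7 of 35 lines. The remaining genes of the rule rose by 0.22 to 0.29 (LOC542856, LOC543096, LOC542781, LOC100125710 and LOC543059) or fell by 0.53 (LOC543127), 0.38 (LOC543145), 0.36 (LOC780602, in another probe set than the one with the line effect), 0.33 (LOC100037638) and 0.32 (LOC543242). XTH, a cell wall enzyme gene, fell by 0.31 (limma adjusted p = 0.0412). When each line was left out in turn, LOC543418 passed in 23 of 35 fits, LOC542856 in 21, LOC543096 in 14, LOC542781 in 12, LOC543145 in 16, LOC543242 in 16 and XTH in 15, and the other genes of this paragraph in 35. With the hybridisation day as a block none of these genes passed, and 4 of the falls turned into rises, as described below.

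In all, 1590 probe sets differed between the replicates (limma, adjusted p under 0.05), 377 higher and 1213 lower in replicate 3, and 3 of them by at least 1 log2 unit. With the hybridisation day as a block the count was 0, as described below. With the 3 prime to 5 prime ratio of the control genes as a covariate the count was 483, with no line block 965, and without the 12 lines with unmatched arrays 805. With that ratio, TPC1, LOC542856, rbcl, Hmgb3 and LOC780602 stayed past the threshold, and the other 11 genes named for a rise or fall kept their direction but no longer passed it. At an unadjusted p under 0.05 there were 11344. Whether the replicate numbers stand for field replications is not given in the sources used here. Leaving out line H5 gave 2874 and G13 gave 2452, while leaving out F82 gave 695, B11 709, H23 744, C31 750, F48 778, A35 840, A77 908, F44 981, C22 995, H8 995 and A91 1027. With quantile normalisation 657 were higher and 1024 lower. Among probe sets with a symbol, 12 were higher and 56 lower, and 10 probe sets passed both the line and the replicate test, where independent lists would share 40.4. The line test had no replicate block, so a shift between replicates lowers its F, and a small overlap is partly built in. Of the tested lists, tubulins were lower as a group (camera adjusted p = 0.0377, higher in 15 of 35 lines), but the adjusted p was 0.511 with an estimated correlation and 0.229 in a permutation test that flipped signs over lines. The camera adjusted p was 0.0523 with median centring and 0.965 with quantile normalisation. TUBA, chosen after its values were seen, fell by 0.16 in 1 probe set (limma adjusted p = 0.0149) and changed by 0.00 in the other (0.992). The count of lists lower or higher was 0 without G32, E5, B68, C31, B33, F44 or H8, 2 without F29, F36, A81, C25, F38b, F38a, F48 or C10, 3 without G30, DH95 or J15, and 4 without H10, H5, D15 or B65. Core histones (camera adjusted p = 0.0638), translation factors and ribosomal proteins with LOC543386 (TEF1) and LOC543485 (eIF4E) (0.0638), and defence and antioxidant proteins (0.0638) did not pass. Neither did embryo and ABA-responsive proteins (0.0944), storage proteins (0.373), gliadins and glutenins (0.373), starch and fructan metabolism (0.373), photosynthesis genes (0.373), peroxidases (0.813) or serpins (0.813). With an estimated correlation, all 11 lists had an adjusted p of 0.511 or more.

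Within these lists, PER1 fell by 0.23 in 1 probe set (limma adjusted p = 0.0426) and by 0.01 in the other (0.929), eIF4E by 0.21 (0.0278), and TEF1 by 0.14 (0.0488), all chosen after their values were seen. Adjusted over the list alone, members passed as follows: photosynthesis genes 6, translation factors and ribosomal proteins 4, green photosynthesis 3, tubulins 2, and 1 each in peroxidases, cell wall, embryo and aleurone, defence and antioxidant proteins and gibberellin 20-oxidases. Over all probe sets in limma, 3 passed in translation and 1 each in photosynthesis genes, tubulins, peroxidases, cell wall, embryo and aleurone, and defence and antioxidant proteins. In storage proteins, starch and fructan metabolism, core histones and the remaining lists 0 passed by either count.

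The replicates were hybridised mostly on different days, and 3 of the 12 days held both, with 22 arrays. With the day as a block, 0 probe sets differed between the replicates in limma (3899 at an unadjusted p under 0.05), and the median SE over probe sets was 0.104 against 0.0507 without it. TPC1 differed by 0.39 with an SE of 0.094 before and by 0.40 with an SE of 0.15 after, so its call ended on precision. Hmgb3 differed by -0.36 with an SE of 0.075 before and by -0.02 with an SE of 0.15 after, and LOC543418 by 0.67 (SE 0.18) before and 0.13 (SE 0.25) after, so these calls ended on size as well. The falls of LOC543127, LOC780602, LOC100037638 and LOC543242 turned into rises of 0.17 (SE 0.28), 0.16 (SE 0.13), 0.09 (SE 0.15) and 0.11 (SE 0.14), and no named gene had a limma adjusted p under 0.777. Tested within those 3 days one at a time, the counts were 0, 1 and 0 (2170, 6748 and 3308 unadjusted). Replicate and hybridisation day cannot be told apart, because most days did not hold both replicates.

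F38a and F38b share the stem of their names, and the labels do not say what the letters mean. In limma, 0 probe sets differed between them (1867 at an unadjusted p under 0.05). F38a is among the 12 lines with unmatched arrays, its arrays sharing 0.541 of the bimodal calls, and its replicate 3 array shared 0.982 with F38b replicate 3, so its mean joins unlike arrays. Among the 630 pairs of lines the median count was 7, the highest 1367, for B33, with its outlying array, against G13, and 115 pairs had 0. Leaving out F38a replicate 3 gave 2. For LOC543395 the difference between F38a and F38b was -0.12, for LOC780595 it was -0.08 and for hsp16.9A it was 3.53, none past the threshold.

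As a test of the line labels, the nearest array to each array was sought. It was the other array of its own line for 23 of 72 arrays, against a mean of 1.02 and a highest count of 10 in 100000 random pairings (permutation p = 1e-05, the smallest these can give). Both arrays of A10, A35, A81, B65, C10, C22, G13 and G30 were nearest to each other. The correlation between the arrays of a line ran from 0.801 in G13 to -0.431 in H5, and F38a replicate 3 was nearest to F38b replicate 1 (r = 0.738).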

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

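The exclusion of 12 lines, the exclusion of the 3 arrays farthest from the mean array, the fits within days and the nearest array by bimodal probe sets were chosen after seeing the data. Counts stayed within 1.5 times the reported one in 14 of 16 other settings for the line effect, 10 of 13 for separate classes, 7 of 15 for replicates, 11 of 11 for F38a against F38b, 9 of 12 for the nearest array, 6 of 11 for lists over lines and 1 of 11 for lists between replicates. The median intraclass correlation moved by less than its spread in 9 of 11. Except where the setting itself removes arrays, lines or calls, the cause was not tested.

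The line effect covered 1553 probe sets, 783 at an adjusted p under 0.01, 2438 without the 12 lines, and 1220 to 3075 without 1 array. The median intraclass correlation of 0.0641 became 0.123 with the day as a block, 0.0240 with the 3 prime to 5 prime ratio, and 0.0521 to 0.118 without 1 array. Separate classes rose from 0 to 3 with 3 lines a side, 3 with 2 arrays out of place, and 135 without the 12 lines. The replicate numbers were not taken to pair arrays of different lines, since the correlation of replicate differences between lines ran from -0.66 to 0.62 and exceeded 0.1 in 38.5% of pairs of lines. With the replicate block the line effect covered 1639 probe sets, the median intraclass correlation was 0.0846, 28 arrays were nearest to their own line, 5 lists passed, and separate classes and F38a against F38b gave 0.

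The replicate count of 1590 became 965 with no line block, 483 with the 3 prime to 5 prime ratio, 805 without the 12 lines (129 higher, 676 lower), 0 with the day as a block, 0 in days with both replicates, 0, 1 and 0 within days 5, 6 and 10, and 695 to 2874 without 1 line. The limma counts of 0 had 3899, 4343, 2170 and 3308 at an unadjusted p under 0.05. With the day as a block, LOC543127 reversed to 0.17, LOC780602 to 0.16, LOC100037638 to 0.09 and LOC543242 to 0.11, and none of the 16 genes named for a rise or fall was past the threshold (adjusted p 0.777 or more). F38a against F38b gave 0 to 2 without 1 array.

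Lists with a line effect numbered 1 with median centring, 1 with the day as a block, 1 with values scaled to SD 1, 0 with list medians, and 0 to 6 without 1 array. Lists shifted between replicates, by camera, numbered 3 with no line block and 0 with median centring, quantile normalisation, both filters, the day as a block, an estimated correlation, the sign-flip test, without the 12 lines and without the lines of the 3 farthest arrays, with 0 to 4 without 1 line. Arrays nearest to their own line numbered 15 over all probe sets, 42 over the top 1 percent by variance and 43 by bimodal agreement.

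Of 37 named line ranges past or short of the threshold, in settings that kept all arrays, PsbP alone changed side, in 3 of them, apart from RPL9 (adjusted p = 0.0498) and hsp16.9A (0.0193) without the 12 lines. Intensity over background limits low probe sets, and a filter on low values left the line count within 1.5 times.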

Other observations

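The bimodal comparison, the matches between lines, the test on array quality and the line test of hsp16.9A were chosen after the result was seen, as were the rate of matches among the 24 other lines, the bound of 0.5 used to exclude a main source and the choice of LOC543477 and FKBP70. hsp16.9A, the small heat shock protein gene, ranged from 3.78 to 13.57 over the 72 arrays, its lowest values close to the bottom of the scale, with a median of 5.36 and 20 arrays above 8. In A91 it was 4.86 in replicate 1 and 12.70 in replicate 3, while in B68 it was high in both, 11.38 and 13.57. Its level moved with 312 probe sets at a correlation over 0.7 in size, 300 of them positively, against 0 in 100 random orders of the arrays. The closest named gene was LOC543477 (r = 0.971, rho = 0.892, both permutation p = 1e-05, the smallest these can give; r = 0.967 without the 2 farthest arrays, 0.975 within days). The lowest of the 18 named probe sets, of 12 other genes, had r = 0.72, 0.669 without the 2 farthest arrays. They were selected on r over 0.7 in size. All had a permutation p of 1e-05, with Benjamini-Hochberg adjustment over these 18 alone. The selection fixed this value in advance, and it does not allow for the probe sets that were searched. FKBP70, a peptidyl-prolyl isomerase gene by its name, followed less closely (r = 0.621, rho = 0.566, both permutation p = 1e-05; 0.563 without the 2 farthest arrays and 0.708 within days).

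The tables argue against hybridisation day as the main source of the hsp16.9A level (permutation p = 0.947, day share of variance -0.109, interval -0.158 to 0.0404). They argue in the same way against RNA degradation, with rho = -0.115 (permutation p = 0.336, interval -0.338 to 0.12; r = -0.165, permutation p = 0.167, -0.13 without the 2 farthest arrays). A smaller part from either stays open. Line stays open too, with an intraclass correlation of 0.235 and an interval from -0.094 to 0.519. Its line test passed without the 12 lines with unmatched arrays (limma adjusted p = 0.0193), which were picked for disagreement between arrays, so this does not settle it. Heat on the plants before sampling might have set the level, and no record of temperature was analysed here.

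Without use of the line labels, 170 probe sets split the 72 arrays into a high and a low level. The 2 arrays of 24 lines shared at least 0.753 of these calls, while those of 12 lines (H5, A91, B11, F38a, E5, A40, F36, G32, C25, J15, DH91 and D15) shared 0.453 to 0.677, no better than 95% of pairs of different lines (limit 0.682). The median of pairs of different lines was 0.541. D15 at 0.677 and DH91 at 0.653 lay well above it, so a lack of match is least clear for them. Of the 24 arrays of these lines, 14 matched an array of another line at 0.753 or more. Examples were F82 replicate 3 with B11 replicate 3 at 0.994 and G32 replicate 1 with H5 replicate 3 at 0.988. At that cut, 13 of the 48 arrays of the 24 lines had such a match among those lines too. The count alone thus does not set exchanged samples apart from lines that are alike. By level the matches were apart, which was looked at after the values were seen. The 14 lay at 0.8235 to 0.994, and those among the 24 lines at 0.818 or less. In other probe sets, 13 of the 14 correlated better with the match than with their own label, where a low value with the own label is partly built in. Their r with the match ran from -0.0615 to 0.763, with a median of 0.479 over the 14 arrays. A pair with both arrays among the 14 entered this median from each side. With each pair entered once, the middle value was 0.313, for E5 replicate 1 with D15 replicate 3. Over arrays, the median was 0.15 for the matches among the 24 lines and 0.325 between the arrays of a line there. The matches were thus not shown to be closer than the arrays of a line. Exchanged or mislabelled samples may explain some of these lines, and mixed seed within a line was not tested. Low array quality as the main source was argued against (rho = -0.131, permutation p = 0.446, interval -0.44 to 0.207; r = -0.0114, permutation p = 0.948, -0.127 without the 2 farthest arrays). Growing conditions that move with hsp16.9A stay open. Without bimodal probe sets that correlate with it, 11 of the 12 lines stayed below the limit, then 0.688. But 144 of the 170 probe sets were kept. Most of these lines agreed too little for the removal to lift them past the limit, so this count cannot decide.

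Of 100 assignments of arrays to lines, 1, the real one, gave as many as 1553 probe sets, and the highest other gave 297. This argues against chance but does not exclude it, because 99 random assignments were run. They also did not keep the arrays of a hybridisation day together. Of 100 exchanges of arrays within lines, 1, the real one, gave as many as 1590 probe sets between replicates, and the highest other gave 245. The exchanges switched each line on its own and did not keep the arrays of a hybridisation day together. They argue against chance among independent lines, but cannot exclude a chance difference between days. With the 3 prime to 5 prime ratio as a covariate, 483 probe sets between replicates remained past the threshold, a large drop. The ratio is 1 index from 7 control genes. The remaining calls therefore cannot tell RNA degradation that it misses from another source, and degradation stays open. With the hybridisation day as a block 0 remained in limma (3899 at an unadjusted p under 0.05), so hybridisation day and replicate cannot be told apart, and a difference between field replications was not tested on its own.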
